A study of Mus musculus with 27 samples.

How the data were processed

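Total RNA from mouse osteosarcomas and their metastases was measured on 27 single-colour Illumina bead arrays, 1 array per tissue sample. Per the labels' protocols, RNA was extracted with Trizol and its quality was inspected on a Bioanalyzer, and the targets carried biotin. Per the labels, the samples form 4 groups: 6 localized primary tumours, 12 primary tumours that gave metastases, 7 lung metastases and 2 liver metastases. The specimen identifier of each sample ties a metastasis to its primary. The labels do not say whether each specimen is a separate animal, so the p-values of single genes measure the spread between specimens.

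The bead files deposited by the authors give, per the file headers, an average signal for each of 45281 probes, which is an un-normalized intensity on a linear scale. The files deposited by the authors also hold a detection score per probe, which runs from 0 to 1 and is high for bright probes, so that 1 minus the score was used as the detection p-value. The number of beads behind each probe is a further deposited column. Per the submitters' processing notes, BeadStudio was among the tools, with no version or role given. The authors' deposited series matrix holds log2 values with the same order of probes as the signal on every array and a median of 5.9 on every array. Its values differed by at most 0.606 from a quantile normalization of the log2 signals made here, without background correction, and it was used as an alternative.

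Probes were named through the platform annotation supplied with the data. Of the 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 had none, and only probes with 1 symbol were named. The Entrez identifiers of 34807 probes matched the RefSeq table (assembly GRCm38.p6), and 0 symbols needed an update. These probes covered 19057 genes. The symbol of the p53 gene, Trp53, was not among the names used, so Trp53 itself was not analysed here.

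Intensities were corrected for background with the neqc function of limma 3.58.1 in R 4.3.3, with the background estimated from the detection p-values and an offset of 16, then put on the log2 scale and quantile normalized between all 27 arrays. A probe counted as detected at a detection p under 0.05. Between 42.6% and 47.5% of the probes were detected per array, and 15483 probes were detected on no array. The median number of beads per probe was 41 to 44. For a gene with several probes, the probe with the highest mean over all arrays was used. A gene was tested where it was detected on at least 6 arrays in the first comparison, 7 in the second and 2 in the liver comparisons. No pair of arrays was a duplicate, with a highest correlation of 0.978 across probes. The number of arrays limits the precision of each value.

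Groups were compared with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Metastatic and localized primaries were compared over their 18 arrays. Lung metastases were compared with their own primaries over 7 pairs with the specimen as a block, because the design text describes that pairing. The 2 comparisons of liver metastases used 21 arrays, the liver and lung metastases and the metastatic primaries, with the specimen as a random block (duplicateCorrelation with statmod 1.5.0, consensus correlation 0.355). The specimen numbers paired the samples: the deviations of the samples of 1 specimen correlated at 0.32 to 0.55, each lung metastasis correlated best with its own primary in 7 of 7 pairs, and detection of the Y-linked Kdm5d matched in 7 of 7 pairs. Where no array of a group detected a gene, its fold is a bound. It sets the mean of the detected group against the mean, per array, of the higher of the lowest detected signal and the gene's own signal, and is written as at least that many fold.

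Before the data were examined, 35 gene lists were fixed: 14 of cell types, 19 of biology and 2 of technical use. They held 740 entries, of which 678 were named on the array, and some genes stand on more than 1 list. Lists with at least 5 tested members were tested with cameraPR on the moderated statistics (preset correlation 0.01), with camera at an estimated correlation and with fry, each adjusted over the lists of a comparison. The list p-values given first are those of cameraPR. They set the members of a list against the other genes and do not measure the spread between specimens. Members were counted as past the threshold over all genes and adjusted over the list alone.

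The genes named in the text follow a rule fixed at the same time. It takes Trp53, which has no value here, and Nkd2, an inhibitor of Wnt signalling, which was chosen from memory of published work on this mouse model and is not independent evidence. It takes the 8 genes with the highest and the 8 with the lowest log2 fold change among those past the threshold, without clone or predicted names and without immunoglobulin and T cell receptor segments. Where fewer than 5 passed in a direction, it takes the 5 with the smallest p. Of each list that passed its test, or had over 20% of its members past the threshold, it takes up to 4 members with the smallest p.

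The procedure was tested on simulated normal values drawn with the residual spread of each gene, with 100 genes changed by a log2 of 1 and 100 by 2. In the paired and liver comparisons a specimen effect was added. In the liver comparison the residual spread already held differences between specimens, so the simulated spread was wider than the real one. Simulated values had no background floor. With 11684 genes in the first comparison it recovered 65% and 84% of them, with 10 false calls among 159. With 11214 genes in the paired comparison it recovered 59% and 92%, with 12 false calls among 163. With 13517 genes in the liver comparison it recovered 24% and 78%, with 11 false calls among 113. Of 200 unchanged lists per comparison, 11, 11 and 5 had a p under 0.05. The simulated genes varied independently of each other, so these lists cannot show how cameraPR behaves for genes that move together. In the first comparison the estimated correlation of the real lists ran from -0.017 for the p53 targets to 0.85 for skeletal muscle.

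The arrays split by their background signal, the level of undetected probes. It was 56.9 to 84.0 on 12 arrays and 41.3 to 50.5 on the other 15. The 12 arrays were 2 localized and 10 metastatic primaries, while 4 localized primaries, 2 metastatic primaries and all 7 lung and 2 liver metastases had the lower background. In 6 of 7 pairs the primary and the lung metastasis therefore differed in background. Background was entered as a covariate, and fits were repeated within the arrays of 1 background, as alternatives chosen after seeing the data. So were fits without 4 primaries low in bone transcripts and without 3 lung metastases with hepatocyte transcripts. Other alternatives, fixed earlier, changed the background correction, the normalization, the detection filter, the choice of probe, the variance model, array weights, the threshold, the specimen block, the specimen prefix and the samples in the fit, or left out each replicate in turn.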

Results

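Gene expression was measured in osteosarcomas, malignant tumours of bone, that arose in mice whose p53 tumour suppressor was altered in the osteoblast lineage. A Cre recombinase active in osteoblasts either removed a floxed p53 allele or switched on a point-mutant one, and the labels do not say which of these each tumour carried. The 27 arrays cover 6 localized primary tumours, 12 primary tumours that gave metastases, 7 lung metastases and 2 liver metastases. Each lung metastasis has its own primary among the 12. Of the liver metastases, that of CR-147 has its own primary and lung metastasis here, while the primary of RF-342 was not analysed here. Between 42.6% and 47.5% of the probes were detected on each array. Levels are log2 normalized intensities with the SD over arrays.

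The first comparison asked which genes differed between primary tumours that gave metastases and those that stayed localized. C1qtnf1, which encodes a secreted protein of the C1q and TNF-related family, was the 1 gene of 11684 that passed the threshold. Its level was 9.70 ± 0.39 (SD, n = 6) in localized primaries and 8.27 ± 0.45 (SD, n = 12) in metastatic primaries. The log2 fold change was -1.43 (SE 0.22, adjusted p = 0.0301), and 12 of 12 metastatic primaries lay below the localized mean. Nkd2, an inhibitor of canonical Wnt signalling, stood at 9.51 ± 2.06 (SD, n = 6) in localized and 8.12 ± 0.82 (SD, n = 12) in metastatic primaries and did not pass (log2 fold change -1.39, SE 0.62, adjusted p = 0.753).

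Transcripts of myeloid and erythroid cells had higher mean levels in the metastatic primaries, a difference that passed by cameraPR alone. No single one of them passed the threshold over all genes. Of 13 measured neutrophil and bone marrow myeloid genes, 0 passed by limma, and 0 when adjusted over the list alone, with a median log2 fold change of 2.0 (adjusted p = 5.65e-09). The call was lost with an estimated correlation (adjusted p = 0.714 with an estimated correlation) and by fry (adjusted p = 0.585 by fry). Among them, S100a9, a calcium-binding protein of neutrophils, had a log2 fold change of 2.69 (SE 0.92, adjusted p = 0.630) and Chil3, a chitinase-like protein of myeloid cells, 2.39 (SE 0.76, adjusted p = 0.630). Of 7 erythroid genes, 0 passed over all genes by limma and 4 were higher when adjusted over the list alone, with a median of 1.5 (adjusted p = 5.17e-06, adjusted p = 0.564 with an estimated correlation, and adjusted p = 0.275 by fry). They were Hbb-b2 and Hba-a1, which encode globin chains, Slc4a1, the anion exchanger of red cells, and Alas2, which starts haem synthesis in red cell precursors, with log2 fold changes of 2.32, 1.5, 3.39 and 2.71. Within the arrays of low background the means of the myeloid and erythroid lists were 4.01 and 1.87, within those of high background 1.92 and 1.65, and with background as a covariate 2.91 and 1.96. The low-background primaries were 4 localized and 2 metastatic, and of the latter RF-104 stood at 12.1 and FC-28 at 8.59 for the myeloid list, against 5.62 to 7.69 in the 4 localized. Without RF-104 the mean of the neutrophil and bone marrow myeloid list over all primaries was 1.58 in place of 1.96. The 18 skeletal muscle genes had a median of 1.03 (adjusted p = 0.0357, and adjusted p = 0.902 with an estimated correlation), with 0 past the threshold and 0 when adjusted over the list alone. Myl1, a myosin light chain of fast muscle, stood at a log2 fold change of 1.80 (SE 1.15, adjusted p = 0.827). The mean of the muscle list was 1.01, and 1.82 within the low-background arrays, 0.37 within the high-background arrays (adjusted p = 0.53) and 1.02 with background as a covariate. Its call was lost without CR-65 (adjusted p = 0.49), RF-56 (0.176), RF-191 (0.0732), CRE-155 (0.164), CR-147 (0.115), RF-212 (0.0687), FC-279 (0.137), CR-45 (0.0553) or RF-104 (0.216).

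None of the other lists with at least 5 measured members passed, with 0 members past the threshold over all genes by limma and 1 lung epithelium gene lower when adjusted over the list alone. The osteoblast and bone matrix genes had a median log2 fold change of 0.54 over 21 members (adjusted p = 0.247), the Wnt genes -0.22 over 28 (adjusted p = 0.247), the p53 targets 0.18 over 19 (adjusted p = 0.413) and the mitosis genes -0.08 over 21 (adjusted p = 0.423). Of the genes with the smallest p that did not pass, Trim10, an erythroid ring-finger protein, was at 2.06 (adjusted p = 0.239), Rps3a1 and Rpl29, ribosomal proteins, at 0.91 and 1.03, and Wdr82 at 2.09, with 3 of 3 other probes of Wdr82 in the opposite direction. On the other side stood Bmx, a tyrosine kinase, at -0.78, Scmh1, a Polycomb protein, at -0.75, Efna5, an ephrin ligand, at -1.22 and Epb41l1, a membrane skeleton protein, at -1.06. In all, 0 genes were higher and 1 was lower by limma, against 340 and 423 at an unadjusted p under 0.05, where 584 are expected with no difference.

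The adjusted p of C1qtnf1 lay near the threshold. The call was lost in 11 of 18 fits that left out 1 primary, with log2 fold changes between -1.53 and -1.30 over the 18 fits and adjusted p between 0.00731 and 0.152. Among the localized primaries, these were the fits without CR-93 (adjusted p = 0.104), RF-44 (0.152), CR-65 (0.0708), RF-191 (0.103) and RF-43 (0.075). Among the metastatic primaries, they were those without CRE-155 (0.0642), CR-147 (0.0668), RF-379 (0.0676), CR-113A (0.0701), RF-229 (0.0735) and RF-104 (0.0721). With background as a covariate the log2 fold change was -1.69 (adjusted p = 0.00798), within the low-background arrays -1.76 (adjusted p = 0.968) and within the high-background arrays -1.62 (adjusted p = 0.158). The call was also lost with the specimen prefix as a covariate (-1.34, adjusted p = 0.184) and in a fit over all 27 arrays (-1.45, adjusted p = 0.152). Over all alternatives the adjusted p ranged from 0.00731 to 0.968. Nkd2 passed within the high-background arrays alone, 10 metastatic against 2 localized primaries, with a log2 fold change of -3.48 (adjusted p = 0.0476), and stood at -0.32 (adjusted p = 0.999) within the low-background arrays. In 4 primaries, CR-65 and RF-56 among the localized and CR-45 and FC-28 among the metastatic, the mean level of the osteoblast genes was 6.67 to 7.23, against 10.4 to 11.4 in the other 14. Without these 4 the C1qtnf1 call was lost (-1.49, adjusted p = 0.0896) and the mean of the skeletal muscle list was -0.09 (adjusted p = 0.942). Without CR-45 alone Trim10 passed (2.24, adjusted p = 0.0405).

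**Figure D1:**
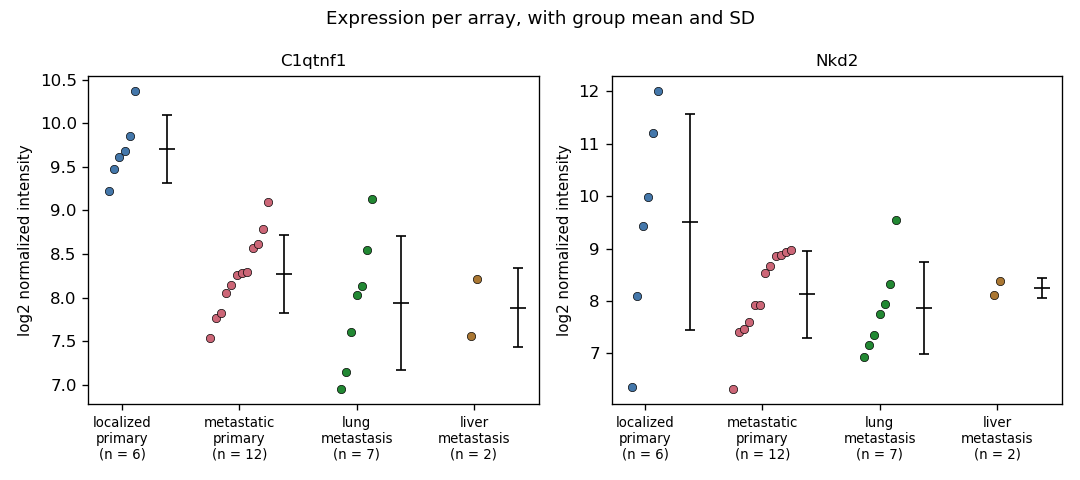
C1qtnf1 and Nkd2 in each array, as log2 normalized intensity on the vertical axis, for the 4 groups on the horizontal axis. Each point is 1 array, and the bar beside the points gives the group mean with its SD. C1qtnf1 averaged 9.70 in the localized and 8.27 in the metastatic primaries, while the Nkd2 levels of the localized primaries had an SD of 2.06.

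The second comparison set each of the 7 lung metastases against the primary tumour of the same specimen. Transcripts of lung epithelium were far more abundant in the lung metastases. Scgb1a1, the secretoglobin of airway club cells, rose from 5.24 ± 1.00 (SD, n = 7) to 15.55 ± 0.22 (SD, n = 7), a log2 fold change of 10.31 (SE 0.33, adjusted p = 3.79e-07). Its probe was the brightest of all on 2 of the 7 lung metastasis arrays and among the first 44 on each, and 2 of 7 primaries detected Scgb1a1, so the fold is less certain in size than in direction. Sftpc, a surfactant protein of alveolar type II cells, rose from 5.07 ± 0.32 (SD, n = 7) to 14.11 ± 0.60 (SD, n = 7), a log2 fold change of 9.04 (SE 0.20, adjusted p = 4.77e-08), with 2 of 7 primaries above background. Transcripts of skeletal muscle were lower. Acta1, the actin of skeletal muscle fibres, fell from 12.71 ± 1.94 (SD, n = 7) to 6.27 ± 1.72 (SD, n = 7), a log2 fold change of -6.44 (SE 0.53, adjusted p = 0.000108), and each of these 3 changes was seen in 7 of 7 pairs.

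Of 18 measured lung epithelium genes, 17 rose and 0 fell, and 17 rose when adjusted over the list alone. Their median log2 fold change was 6.31, or 5.99 with 6 members at their bound (adjusted p = 1.67e-168, and adjusted p = 0.0365 with an estimated correlation). Sftpd, a collectin of surfactant, rose by 9.43, Wfdc2, a secreted protein of airway epithelium, by 8.16 and Cyp2f2, a cytochrome P450 of club cells, by 7.59 on the log2 scale, with 2, 3 and 1 of 7 primaries above background, so these folds are less certain in size than in direction. Cxcl15, a lung chemokine, was at least 216-fold higher, Sec14l3 at least 217-fold and Sftpb, a surfactant protein, at least 199.9-fold. Of 13 genes of lung endothelium and stroma, 7 rose and 0 fell, and 10 rose when adjusted over the list alone, with a median of 1.87 (adjusted p = 8.96e-07, and adjusted p = 0.553 with an estimated correlation). Tbx4, a transcription factor of lung mesenchyme, was at least 18.9-fold higher, and Car4, a carbonic anhydrase of lung capillaries, rose by 4.22 on the log2 scale. Of 18 endothelial and pericyte genes, 6 rose and 0 fell, and 10 rose when adjusted over the list alone, with a median of 1.10 (adjusted p = 0.000233, and adjusted p = 0.553 with an estimated correlation). Vwf, the clotting factor of endothelial cells, rose by 3.26, and Mcam, an adhesion molecule of vessels, by 1.30, a call lost without the RF-364 pair (adjusted p = 0.0595).

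Of 17 skeletal muscle genes, 14 fell and 0 rose, and 17 fell when adjusted over the list alone. Their median log2 fold change was -4.14 (adjusted p = 2.57e-19, and adjusted p = 0.553 with an estimated correlation). The lowest fold changes after that of Acta1 were those of Atp2a1, the calcium pump of fast fibres, at -5.69, Tnnc2 and Tnnt3, troponins, at -5.56 and -4.98, Mb, myoglobin, at -4.91, Pvalb, a calcium buffer of fast fibres, at -4.88, and Mylpf and Myl1, myosin light chains, at -4.78 and -4.27. All 7 fell in 7 of 7 pairs, and between 1 and 7 of the 7 lung metastases detected each of them. The erythroid and myeloid lists, whose genes are expressed in bone marrow and its blood cells, did not pass and had medians of 0.26 (adjusted p = 0.535) and 0.90 (adjusted p = 0.075).

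Of 16 hepatocyte genes, 4 rose and 0 fell, and 14 rose when adjusted over the list alone, with a median of 2.57 (adjusted p = 3.56e-05, and adjusted p = 0.553 with an estimated correlation). Hp, haptoglobin, rose by 2.72 (SE 0.49, adjusted p = 0.011) and Hpx, hemopexin, by 3.14 (SE 0.72, adjusted p = 0.0319), both plasma proteins made by the liver. The call for Hpx was lost without the CRE-155, RF-212, RF-364 or RF-379 pair (adjusted p 0.0522 to 0.0794). Levels of the list lay at 8.91, 9.56 and 8.79 in the lung metastases RF-364, CR-147 and RF-379 and between 5.80 and 6.85 in the other 4. Without these 3 pairs the list mean moved from 2.39 to 0.82 and the call was lost (adjusted p = 0.176).

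Of 5 B and plasma cell genes, 4 rose, and 4 rose and 1 fell when adjusted over the list alone, with a median of 1.43 (adjusted p = 0.075, adjusted p = 0.553 with an estimated correlation, and adjusted p = 0.0206 without the CR-147 pair). Mzb1, a chaperone of antibody-secreting cells, rose by 1.63 and Blk, a kinase of B cells, by 1.51, and both calls were lost without the CRE-155, FC-279, RF-212, RF-364 or FC-28 pair (adjusted p 0.0531 to 0.115). Within the low-background arrays the list mean was 0.010. Of 16 basement membrane genes, 6 rose and 0 fell, and 6 rose when adjusted over the list alone, with a median of 0.18 and a mean of 0.75 (adjusted p = 0.00631, and adjusted p = 0.553 with an estimated correlation). Lamb3, a laminin chain of epithelia, rose by 4.79 and Col4a3, a collagen IV chain of alveolar and glomerular membranes, was at least 4.94-fold higher. The list did not pass without the 3 pairs with hepatocyte transcripts (adjusted p = 0.173), with background as a covariate (adjusted p = 0.0702) or within the low-background arrays (adjusted p = 0.437).

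Of 17 genes of the epithelial-mesenchymal transition list, 7 rose and 1 fell, over all genes and adjusted over the list alone, with a median of 0.03 and a mean of 1.24 (adjusted p = 2.2e-13, and adjusted p = 0.553 with an estimated correlation). The members with the smallest p were Cldn3, a tight junction protein, at least 23.9-fold higher, Krt19 and Krt18, keratins of simple epithelia, at 3.78 and 4.15, and Cdh1, the epithelial cadherin, at 3.97. All 4 are epithelial genes. Of 5 keratinocyte and skin genes, Cdh1 rose and Trp63, a transcription factor of basal epithelia, fell by 1.27, with 1 in each direction also when adjusted over the list alone. The median was -0.31 and the mean 0.38, and the list did not pass (adjusted p = 0.0762, adjusted p = 0.987 with an estimated correlation, and adjusted p = 0.00211 without the FC-28 pair, upward). The call for Trp63 was lost without the CRE-155, FC-279, RF-364 or CR-147 pair (adjusted p 0.0555 to 0.063).

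Genes of the cell cycle stood lower in the lung metastases as lists, with few members past the threshold. Of 21 proliferation and mitosis genes, 1 fell and 0 rose, also when adjusted over the list alone, with a median of -0.82 (adjusted p = 0.00192, and adjusted p = 0.644 with an estimated correlation). Ccna2, cyclin A, fell by 0.92 (SE 0.20, adjusted p = 0.0244) in 7 of 7 pairs, a call lost without the FC-279, RF-212 or RF-364 pair (adjusted p 0.0553 to 0.0578). Of 26 DNA replication genes, 1 fell and 0 rose, also when adjusted over the list alone, with a median of -0.82 (adjusted p = 0.000839, and adjusted p = 0.644 with an estimated correlation). Prim1, a primase subunit, fell by 0.64 (SE 0.14, adjusted p = 0.0236) in 7 of 7 pairs, a call lost without the CRE-155, FC-279, RF-212 or RF-379 pair (adjusted p 0.0542 to 0.0779). The lung epithelium list stood higher in the same pairs, with its median of 6.31. The proliferation and mitosis list stood at 5.73 in the lung metastasis of FC-28 and at 7.95 in its primary. Without the FC-28 pair the mean of the proliferation and mitosis list was -0.47 in place of -0.78 (adjusted p = 0.0137) and that of the DNA replication list -0.44 in place of -0.70 (adjusted p = 0.0085). These means were -0.49 and -0.44 with arrayWeights, and -1.25 and -1.15 without the 3 pairs with hepatocyte transcripts. Nkd2 stood at 8.19 ± 0.62 (SD, n = 7) in the primaries and 7.86 ± 0.88 (SD, n = 7) in the lung metastases and did not pass (log2 fold change -0.33, SE 0.43, adjusted p = 0.639).

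The other lists with at least 5 measured members did not pass. In all, 639 of 11214 genes rose and 291 fell in the lung metastases, against 1452 and 1485 at an unadjusted p under 0.05. For 71 of the higher and 4 of the lower genes, 1 side was not above background. Without the specimen block 444 rose and 85 fell, and with median scaling in place of quantile normalization 643 rose and 2022 fell, so that 24.1% of the calls were higher in place of 68.7%. The median log2 fold change of all genes was -0.32 with that scaling and -0.06 otherwise. Leaving out the pair CRE-155, FC-279, RF-212, RF-364, CR-147 or RF-379 left 174, 83, 97, 102, 164 or 168 lower genes, and leaving out RF-212 left 391 higher genes. With background as a covariate over all 27 arrays 531 rose and 177 fell. Within the low-background arrays, 7 lung metastases were set against 2 metastatic primaries, and 162 genes rose and 16 fell. The 4 localized primaries and 2 liver metastases of low background were also in that second fit. Scgb1a1 stood at 10.47 and 10.66 in these fits, Sftpc at 8.95 and 8.81, and Acta1 at -5.83 (adjusted p = 0.0281) and -6.21 (adjusted p = 0.152). The list means there were 5.78 and 5.44 for lung epithelium, -3.67 and -3.96 for skeletal muscle, 2.34 and 1.96 for lung endothelium and stroma, 1.27 and 1.07 for endothelial and pericyte genes, 1.97 and 1.92 for hepatocyte genes, 1.02 and 0.76 for the epithelial-mesenchymal transition list, -0.89 and -0.56 for proliferation and mitosis and -0.93 and -0.72 for DNA replication.

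The third comparison set the 2 liver metastases against the 12 metastatic primaries. Transcripts of hepatocytes were far more abundant in the liver metastases. Mat1a, which makes S-adenosylmethionine in the liver, rose from 5.02 ± 0.68 (SD, n = 12) to 14.78 ± 0.33 (SD, n = 2), a log2 fold change of 9.66 (SE 0.54, adjusted p = 6.88e-12), with 3 of 12 primaries above background. Muscle transcripts were lower, with Myl1 at 12.44 ± 2.01 (SD, n = 12) in the primaries and 5.81 ± 1.54 (SD, n = 2) in the liver metastases (log2 fold change -6.92, SE 1.32, adjusted p = 0.000776). Both changes were seen in 2 of 2 liver metastases. Nkd2 stood at 8.24 ± 0.19 (SD, n = 2) in the liver metastases and did not pass (log2 fold change 0.09, SE 0.61, adjusted p = 0.955).

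Of 25 hepatocyte genes, 24 rose and 0 fell, and 25 rose when adjusted over the list alone. Their median log2 fold change was 7.14, the same with 8 members at their bound (adjusted p = 4.17e-31, and adjusted p = 0.0334 with an estimated correlation). Fga, a fibrinogen chain, rose by 9.62, Apoa1 and Apoc3, apolipoproteins, by 9.5 and 9.44, Ttr, a carrier of thyroid hormone, by 9.48, Hpx by 9.46, Azgp1, a secreted glycoprotein, by 9.43 and Itih3, a plasma protease inhibitor chain, by 9.31. These folds are less certain in size than in direction, since 3 or 4 of the 12 primaries detected each gene, and 7 detected Hpx. In the liver metastases Apoa1 ranked 12 and 19 and Ttr 14 and 40 among all probes by brightness. Apob, the apolipoprotein of low-density lipoprotein, was at least 189.6-fold higher and Tdo2, which degrades tryptophan, at least 7.59-fold.

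Of 19 skeletal muscle genes, 4 fell and 1 rose, and 13 fell and 1 rose when adjusted over the list alone. The median was -4.02, or -3.73 with 8 members at their bound (adjusted p = 0.0455, and adjusted p = 0.986 with an estimated correlation). The member that rose was Myh7, the slow myosin heavy chain, at least 1.53-fold higher. Next to Myl1, the lowest fold changes were those of Acta1 at -6.11 and Atp2a1 at -5.32. Mb was at least 28.7-fold lower, Flnc, a filamin of muscle, at least 27.1-fold, Ppp1r27, a phosphatase regulator, at least 5.11-fold and Mfap5, a microfibril protein, at least 7.77-fold, and Cpxm1, a carboxypeptidase-like protein, was at -3.17. Of these 8 genes, Myl1 alone passed without either liver metastasis in turn. The other 7 did not pass without CR-147 (adjusted p 0.0648 to 0.485), and all but Flnc did not pass without RF-342 (adjusted p 0.134 to 0.254).

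Lung epithelium genes were also higher in the liver metastases: of 19, 9 rose and 0 fell, and 13 rose when adjusted over the list alone. The median was 1.82, or 1.05 with 4 members at their bound (adjusted p = 0.00791, and adjusted p = 0.966 with an estimated correlation). Cyp2f2, which the liver also expresses, rose by 6.07 and Sftpd by 4.17. Sftpc stood at 10.7 in the liver metastasis of CR-147 and at 4.84 in that of RF-342, and Scgb1a1 at 13.0 and 4.90. The mean of the lung epithelium list was 1.83, and 2.88 without RF-342. Without CR-147 the call of the list was lost (mean 0.50, adjusted p = 0.41), Sftpd did not pass (2.16, adjusted p = 0.337), and Sftpc was at -0.24 (adjusted p = 0.93) in place of 3.27 (adjusted p = 0.00917).

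Of 8 B and plasma cell genes, 3 rose, and 4 rose when adjusted over the list alone, with a median of 1.30, or 1.06 with 3 members at their bound (adjusted p = 0.471, adjusted p = 0.986 with an estimated correlation, and adjusted p = 0.00152 without CR-147). Ms4a1, a surface protein of B cells, was at least 1.31-fold higher, a call that rested on RF-342 at 6.48, with CR-147 at 4.74 not above background. It was lost with background as a covariate (adjusted p = 0.129), within the low-background arrays (adjusted p = 0.486) and without the primaries CR-45 and FC-28 (adjusted p = 0.053), and without RF-342 the gene was not tested. Mzb1 rose by 2.90, a call lost without RF-342 (adjusted p = 0.773). Of 10 adipocyte genes, 3 rose, also when adjusted over the list alone, with a median of 0.22 (adjusted p = 0.471). They were Pck1, an enzyme of glucose synthesis, at 3.47, Dgat2, an enzyme of triglyceride synthesis, at 3.35, a call lost without CR-147 (adjusted p = 0.0923), and Thrsp, a regulator of lipid synthesis, at 3.25, a call lost without CR-147 (adjusted p = 0.0626) or RF-342 (adjusted p = 0.387). Liver also expresses all 3. Of 18 genes of the epithelial-mesenchymal transition list, 4 rose and 1 fell, and 5 rose and 3 fell when adjusted over the list alone, with a median of -0.37 and a mean of 0.92 (adjusted p = 0.465, adjusted p = 0.986 with an estimated correlation, and adjusted p = 0.0281 without RF-342). Cldn3 was at least 44.8-fold higher and Krt8, a keratin of simple epithelia, rose by 7.04.

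No other list with at least 5 measured members passed. In all, 958 of 13517 genes rose and 307 fell in the liver metastases, against 1423 and 1397 at an unadjusted p under 0.05. For 237 of the higher and 23 of the lower genes, 1 side was not above background. Without CR-147, 502 rose and 62 fell, and without RF-342, 770 rose and 88 fell. The median log2 fold change of all genes was -0.17, and with median scaling it was -0.27, with 65.2% of the calls higher in place of 75.7%. With background as a covariate 715 rose and 161 fell. Within the low-background arrays, 2 liver metastases were set against 2 primaries, with the 7 lung metastases also in the fit, and 598 genes rose and 130 fell. Mat1a stood at 9.80 and 10.02 in these fits, Myl1 at -7.21 (adjusted p = 0.0147) and -6.39 (adjusted p = 0.155), and the list means were 6.58 and 7.15 for hepatocyte genes, -4.23 and -4.02 for skeletal muscle and 1.85 and 1.45 for lung epithelium.

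**Figure D2:**
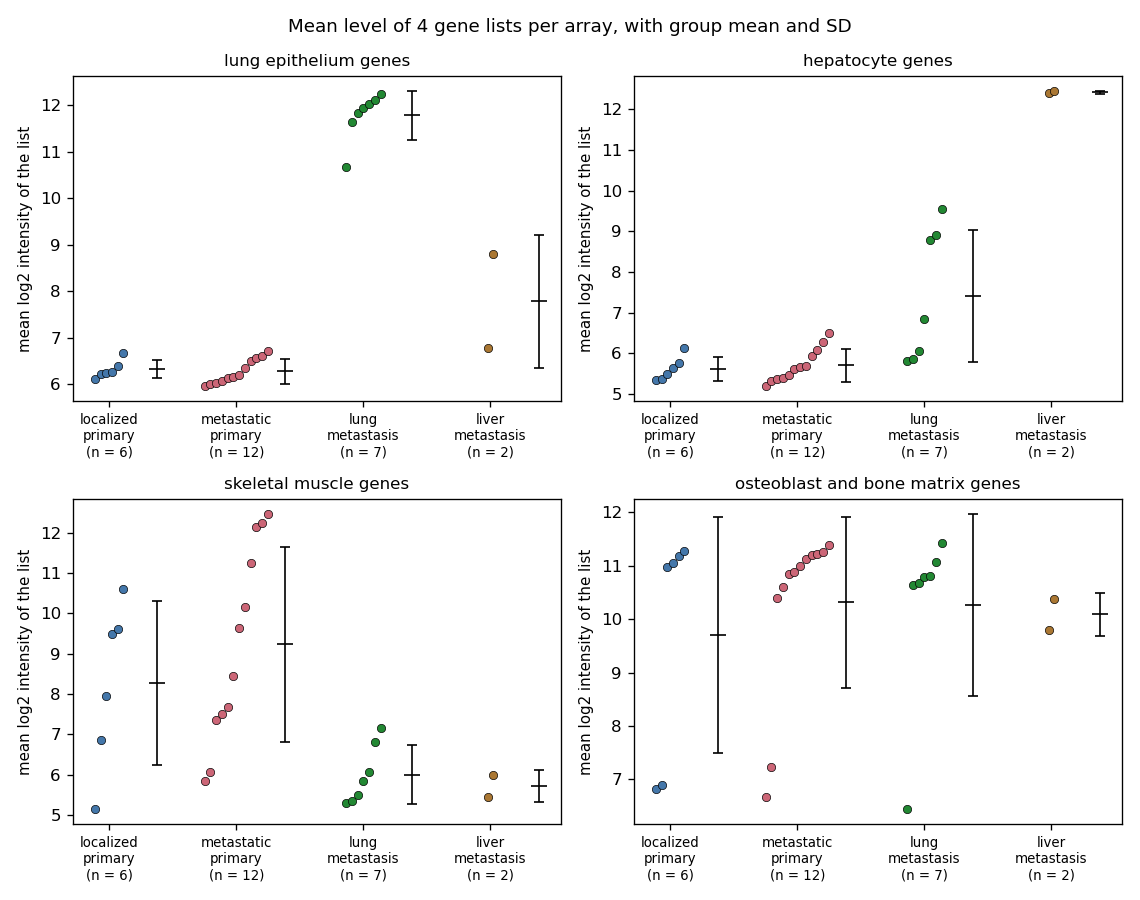
Mean level of 4 gene lists in each array, as mean log2 intensity on the vertical axis, for the 4 groups on the horizontal axis. Each point is 1 array, and the bar beside the points gives the group mean with its SD. Lung epithelium genes averaged 11.8 in the lung metastases and hepatocyte genes 12.4 in the liver metastases, while the osteoblast genes lay between 6.67 and 7.23 in 4 primaries.

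The fourth comparison set the 2 liver metastases against the 7 lung metastases, all of them low-background arrays. Liver enzymes and apolipoproteins were higher and surfactant proteins lower in the liver metastases. Cyp2d26, a cytochrome P450 of the liver, stood at 12.86 ± 0.27 (SD, n = 2) in liver and 5.65 ± 1.43 (SD, n = 7) in lung metastases (log2 fold change 6.96, SE 0.62, adjusted p = 2e-08). Sftpb stood at 6.25 ± 2.16 (SD, n = 2) in liver and 12.86 ± 0.79 (SD, n = 7) in lung metastases (log2 fold change -6.17, SE 0.55, adjusted p = 2.31e-08). Nkd2 did not pass (log2 fold change 0.38, SE 0.63, adjusted p = 0.858).

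Of 25 hepatocyte genes, 22 rose and 0 fell, and 25 rose when adjusted over the list alone, with a median of 5.27 (adjusted p = 1.7e-21, and adjusted p = 0.0563 with an estimated correlation). The lung metastases RF-364, CR-147 and RF-379 themselves held hepatocyte transcripts, with list levels of 8.91, 9.56 and 8.79 against 5.80 to 6.85 in the other 4. Without these 3 the mean of the hepatocyte list was 6.76 in place of 5.08, and Cyp2d26 was at 8.36. That Cyp2d26 fold is less certain in size than in direction, since the lung level it implies lies near that of undetected genes. Without these 3, 701 genes rose and 578 fell. Apoc3 rose by 7.03, Cps1, the entry enzyme of the urea cycle, by 6.97, Cyp2c70, which hydroxylates bile acids, by 6.84, Serpinf2, the plasmin inhibitor, by 6.77 and Fga by 6.71, with each of the 5 above background in 3 or 5 of the 7 lung metastases. Of 19 lung epithelium genes, 12 fell and 0 rose, and 14 fell when adjusted over the list alone, with a median of -4.27 (adjusted p = 1.34e-15, and adjusted p = 0.02 with an estimated correlation). Sec14l3 fell by 6.24, Cldn18, a tight junction protein of alveoli, by 5.37 and Scgb1a1 by 6.00, a call lost without RF-342 (-2.44, adjusted p = 0.158), and these 3 were above background in 1 of the 2 liver metastases. Of 18 endothelial and pericyte genes, 7 fell and 0 rose, and 10 fell when adjusted over the list alone, with a median of -1.60 (adjusted p = 0.00322, and adjusted p = 0.552 with an estimated correlation). Cldn5, the claudin of endothelial junctions, fell by 2.97, and Mcam by 1.98, a call lost without CR-147 (adjusted p = 0.0986). Of 13 genes of lung endothelium and stroma, 5 fell and 0 rose, and 9 fell when adjusted over the list alone, with a median of -1.96 (adjusted p = 0.00432, and adjusted p = 0.552 with an estimated correlation), among them Tbx4, which fell by 4.05.

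Of 17 basement membrane genes, 5 fell and 1 rose, and 6 fell and 1 rose when adjusted over the list alone, with a median of -0.53 (adjusted p = 0.0843, adjusted p = 0.552 with an estimated correlation, and adjusted p = 0.0497 without CR-147). Col4a2 and Col4a1, the widespread collagen IV chains, fell by 1.93 and 1.51, and Col4a3 was at least 4.65-fold lower. Of 10 adipocyte genes, 3 rose, also when adjusted over the list alone, with a median of 0.08 (adjusted p = 0.477), and of these Pck1 stood at 3.12 and Dgat2 at 3.65, both calls lost without CR-147 (adjusted p = 0.0948 and 0.0675). No other list with at least 5 measured members passed. In all, 779 of 13517 genes rose and 439 fell in liver against lung metastases, against 1219 and 1366 at an unadjusted p under 0.05. Without CR-147, 374 rose and 135 fell, and without RF-342, 610 rose and 140 fell.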

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

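The tests of liver RNA in 3 lung metastases and of lung RNA in 1 liver metastasis were chosen only after the result was seen.

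In 7 of 118 sets of values, 1 sample stood apart from the rest of its group by Dixon's test, and chance does so in about 1 of 20 sets. All 7 lie among the lung metastases, and 3 of them are values of FC-28. In FC-28, Vwf reached 13.7 with the next sample at 11.6, and Flt1, a receptor for vascular growth factor, reached 13.8 with the next at 12.0. The genes of lung endothelium and stroma averaged 11.5 there, with the next sample at 9.70. In CR-147, Cldn3 was lowest at 8.65 with the next sample at 9.81, and the lung epithelium genes were lowest at 10.7 with the next at 11.6. Tnnt3 reached 6.13 in RF-212 with the next sample at 5.25. Cidec, a lipid droplet protein, reached 9.66 in CRE-155 with the next sample at 6.95.

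Transcripts of 1 metastatic site appeared in samples of the other and, at lower levels, in some primaries. Alb, serum albumin, was chosen after its values were seen and stood at 8.71, 8.99 and 7.36 in the lung metastases RF-364, CR-147 and RF-379 and between 4.50 and 4.57 in the other 4, and Apoa1 at 12.2, 13.3 and 12.2 against 4.67 to 7.95. Apoa1 and Ttr also stood at 7.65 and 7.43 in the primary of RF-364, 6.94 and 7.08 in that of RF-379, 8.35 and 8.44 in that of RF-89 and 6.54 and 6.32 in that of CR-93. In the primary of CR-147 they stood at only 4.58 and 4.56, although its lung metastasis had the highest Apoa1 of the lung metastases. Scgb1a1 stood at 7.07 in the primary of RF-379, 8.43 in that of RF-89 and 6.22 in that of FC-279. Of 25 hepatocyte genes, 20 (80%) lay in each of the 3 above the highest of the other 4, at the bound set for liver RNA and not over it, and of 18 lung epithelium genes 14 (77.8%) were higher in the liver metastasis of CR-147, the 1 specimen here with metastases at both sites, than in that of RF-342, under the same bound. The samples were picked by these same transcripts, so the counts of members restate the pattern and do not test its cause. Transcripts of the other site were thus present in these samples, and how they came there was not settled. Liver or lung tissue in the lesion, RNA carried over in handling and a difference between the specimens cannot be told apart, and no biological explanation was tested.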

How the results depend on the processing

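Alternatives for array background, for the 4 primaries low in bone transcripts and for hepatocyte transcripts were chosen after seeing the data. Where no reason is given, the cause was not tested. A chip or slide block was not run, as neither is given in the files used. Signal over background limits genes detected in 1 group to a bound. Over the alternatives, 725, 922, 481 and 458 values of named genes kept direction and side of the threshold in the 4 comparisons, 16, 171, 71 and 19 lost the call, 2, 17, 1 and 0 gained it and 1, 27, 5 and 1 turned direction. A gene or list that passed in neither fit counts as kept, so these counts do not measure how well the calls held. In the first comparison C1qtnf1 was the 1 named gene past the threshold, so all 16 lost calls there are its own. For lists, 78, 205, 71 and 71 kept both, 21, 18, 15 and 3 lost the call, 0, 6, 3 and 4 gained it and 1, 6, 0 and 0 turned direction.

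In the first comparison 0 genes were lower with the prefix as a covariate, over all 27 arrays, within the low-background arrays or without the 4 primaries. Within the high-background arrays 1 gene was higher (Arhgap44, named after its value was seen) and 14 lower, 0 of them shared. Leave-outs gave 0 to 1 higher and 0 to 1 lower genes. Without the 4 primaries Mylpf was at -0.10 and the skeletal muscle list at -0.0866.

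For the lung metastases, lower genes numbered 2022 with median scaling, 449 with all probes, 452 with arrayWeights, 89 at 2-fold or more and 85 without the replicate block, which also took the call from Sox7, from B cell and hepatocyte genes and from Ccna2 and Prim1. All 27 arrays gave 1146 higher and 967 lower genes, of which 595 and 255 were shared. Leave-outs gave 391 to 629 higher and 83 to 252 lower genes. Without the 3 pairs with hepatocyte transcripts 414 were higher and 56 lower. All 27 arrays with background as a covariate gave 177 lower genes, and the low-background arrays 162 higher and 16 lower. With the lung lists removed and a lung score as a covariate, 2 genes were higher (Apoa1 and Ttr) and 1 lower (Slc4a1), named after their values were seen, since the score follows the group by construction. Its fold changes have no meaning as sizes: Mzb1 -9.29, Blk -5.33, Cd79b -6.88, Cd22 -6.75, Vwf -3.60, Mcam -3.33, Flt1 -7.60, Esam -9.16, Cdh1 -1.20, Col4a3 -0.92, Cldn3 -0.10, Lor 3.20, Ccna2 2.19, Ttk 1.80, Tpx2 9.17, Prim1 1.38, Rrm2 5.02, Cdt1 6.34 and Ccne1 4.09, with list means of -5.05 for B and plasma cell, -6.63 for endothelial and pericyte, -1.42 for keratinocyte and skin, 7.14 for proliferation and mitosis and 6.36 for DNA replication. Krt14 was at 0.045 without the 3 pairs, 1.08 within low-background arrays and -0.60 to 0.051 in leave-outs, and Lor, a keratinocyte gene, at -0.75 to 0.083. With background as a covariate Nkd2 was at 1.07. Within low-background arrays Blk was at -0.58, Cd79b at -0.016, Cd22 at -0.049 and the B and plasma cell list at 0.010.

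For liver against primaries, lower genes numbered 476 with median scaling, 487 with arrayWeights and 161 with background as a covariate, and the low-background arrays gave 598 higher and 130 lower. Leaving out 1 liver metastasis leaves a lone sample assumed to vary like the other groups, and gave 502 to 770 higher and 62 to 88 lower genes. Nkd2 was at -0.019 with median scaling, -0.0093 with arrayWeights, -0.18 without CR-45 and FC-28, and -0.019 to 0.17 in leave-outs, and Sftpc at -0.24 to 6.02. For liver against lung, all probes gave 1208 higher and arrayWeights 708 lower genes, leave-outs gave 374 to 610 higher and 135 to 140 lower, and Cidec was at -2.06 to 4.23. Without the replicate block, Mb, Atp2a1, Ppp1r27, Acta1, Cd22, Mzb1, Abca3 and the skeletal muscle and lung epithelium lists lost their call against primaries, and Thrsp lost it against lung.

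Lists past the threshold numbered 3, 9, 3 and 4 in the 4 comparisons, 0, 1, 1 and 1 with an estimated correlation, and 0, 5, 2 and 9 by fry.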

Other observations

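The tests of array background, of failed arrays and of tissue of a listed cell type were chosen only after the result was seen.

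Several gene groups that did not pass as lists in the lung metastases still held single genes past the threshold. Over all genes tested there, 8.29% passed. The osteoblast (5%), fibrillar matrix (4.35%) and p53 target (5.56%) lists held a smaller share, and the Notch (14.3%) and adhesion (16%) lists a larger one. These shares were not particular to the Notch and adhesion lists. Hedgehog (20%), chemokine (19%), erythroid (16.7%) and neutrophil (15.4%) lists that did not pass held like or larger shares. So did the technical list of handling stress (15.8%). Of 20 osteoblast and bone matrix genes, 1 rose and 0 fell, with a median log2 fold change of -0.41 (adjusted p = 0.372), and the list averaged 10.27 ± 1.71 (SD, n = 7) in the lung metastases and 10.54 ± 1.47 (SD, n = 7) in their own primaries, lower in 6 of 7 pairs. Of 14 Notch pathway genes, 2 rose, with a median of 0.50 (adjusted p = 0.075). Of 25 genes of adhesion and cytoskeleton linked to metastasis, 4 rose and 0 fell, with a median of 0.06 (adjusted p = 0.267). Of 23 fibrillar matrix genes, 1 fell, with a median of -0.57 (adjusted p = 0.075), and of 18 p53 targets 1 rose, with a median of 0.04 (adjusted p = 0.9).

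Between liver and lung metastases, the Notch, TGF-beta and BMP, Hedgehog, and adhesion and cytoskeleton lists moved on balance downward by the fry test without passing against other genes. The adjusted p by fry was 0.0348 for the 17 Notch pathway genes, with a median of -0.77, and 0.0302 for the 24 TGF-beta and BMP genes, with a median of -0.49. It was 0.0375 for the 10 Hedgehog genes, with a median of -0.60, and 0.0348 for the 27 genes of adhesion and cytoskeleton, with a median of -0.50. The adjusted p against other genes was 0.0843, 0.349, 0.349 and 0.182 for the same 4 lists, and with an estimated correlation 0.555, 0.555, 0.717 and 0.555. The 32 canonical Wnt genes had a median of -0.11 (adjusted p = 0.963 by fry). In the same comparison the endothelial and pericyte list, at -1.60, and the lung endothelium and stroma list, at -1.96, stood lower.

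The genes that differ between lung metastases and their own primaries held a lung epithelium list with a median log2 fold change of 6.31, so lung tissue in the lung specimens may account for the lung genes among them. Loss of the tissue around the primary was left open, with the muscle list at -4.14, while the erythroid and myeloid lists, at 0.26 and 0.90, did not pass and do not decide it, since lung tissue holds blood cells of its own. Within the low-background arrays the genes past the threshold had a median log2 fold change of 1.02 in the direction of the paired fit (quartiles 0.41 and 2.17), and 849 of 926 kept that direction. That fit reused the 7 lung metastases and the FC-28 primary that had picked the genes, so part of this agreement was built in. Both arrays of the FC-28 pair have a low background. Of 857 genes that passed without that pair, 781 (91.1%) went the same direction in it. This argues against array background as the whole cause, on 1 pair whose primary is low in bone transcripts. With background as a covariate, 380 of the 930 genes (40.9%) still passed in the same direction, against 850 in the same fit without it, and for the 550 that did not pass the median went from 0.96 to 0.72 and the median SE from 0.27 to 0.41, so their calls ended with both a smaller fold and a larger error. A part of background in the folds of these 550, whose median was 0.49 within the low-background arrays, was not settled, because 6 of 7 pairs differ in background, and muscle at the bone site stays an untested biological difference between the tissues.

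Osteoblast transcripts were low in 4 primaries: Ibsp, bone sialoprotein, stood at 4.57 in CR-65, 4.84 in RF-56, 4.98 in CR-45 and 7.87 in FC-28, against 14.1 to 15.3 in the other 14, and Sp7, a transcription factor of osteoblasts, at 4.47 to 4.94 against 11.6 to 13.7, while Col1a1 and Col1a2, collagen chains of bone and other connective tissue, were lower but well present, at 9.90 to 12.9 against 14.2 to 15.6 and at 7.75 to 10.8 against 11.9 to 15.2. Among genes that, like these 4, were chosen after their values were seen, the same 4 held more Mmp3, a matrix protease, at 12.7, 13.4, 12.3 and 14.1 against 5.63 to 9.22, more Met, the receptor for hepatocyte growth factor, at 12.4, 6.86, 12.4 and 10.3 against 4.42 to 5.06, more Prl2c3, a prolactin family hormone, at 15.3, 13.1, 13.9 and 11.1 against 4.47 to 10.1, more Lgals7, a galectin of stratified epithelia, at 10.7 to 11.9 against 4.71 to 6.97, and more Crabp1, a retinoic acid binding protein, at 9.73 to 11.6 against 4.54 to 8.91, while Sox10, a transcription factor of the neural crest, stood at 4.65, 10.7, 9.61 and 7.98 against 4.52 to 5.66. Tissue of 1 listed cell type in place of tumour in all 4 did not show, since 0 cell type lists lay above the other 14 in all 4. This cannot exclude such tissue, because the other 14 themselves reached 12.5 for skeletal muscle and 11.4 for macrophages and monocytes. The keratinocyte and skin list lay above them in 1, CR-45, at 7.84 against 5.12 to 6.71, which leaves other tissue in single tumours open. Levels of other lists argue against failed arrays or poor RNA as the whole cause. The ribosomal protein list stood at 12.8 to 12.9 in the 4, within the 12.6 to 13.1 of the other 14. The adhesion and cytoskeleton list stood at 9.4 to 9.6, above their 8.41 to 8.96. The endothelial and pericyte, lung endothelium and stroma, and adipocyte lists lay below the other 14 in all 4. A part of failed arrays or poor RNA was not settled. CR-65 and FC-28, 2 of the 4 arrays, lay below the lowest percentage of probes detected in the other 14. RF-56 at 46.4% lay within their 44.2% to 46.9% and CR-45 at 47.5% above them. Tumours of another cell lineage stay open, and no biological explanation was tested, since the labels give no group that sets the 4 apart.

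In FC-28 the lung metastasis was also low in them, with Ibsp at 4.76 and Sp7 at 4.54. Alpl, the alkaline phosphatase of bone, stood at 7.71 there, Col1a1 at 8.90 and Col1a2 at 6.24, against 11.6 to 13.3, 14.9 to 15.6 and 13.1 to 14.9 in the other lung metastases. Of the transcripts that stood high in its primary Met was at 4.66 and Prl2c3 at 4.63, while Mmp3 at 7.86 lay within the 6.32 to 8.54 of the other lung metastases. Bdnf, a neurotrophin, stood at 8.44 in the primary of FC-28, against 4.52 to 5.06 in the 14 other primaries, and at 9.57 in its lung metastasis, against 5.66 to 8.12 in the other lung metastases. All other lung metastases thus also lay above those 14 primaries, so Bdnf does not tie this lung metastasis to its primary. Top2a, a topoisomerase of dividing cells, was like Bdnf and Alpl chosen after its values were seen. It stood at 6.20 in the lung metastasis of FC-28 and at 9.31 to 10.8 in the others. The lung metastasis of FC-28 also stood at 12.3 for the lung epithelium list, against 10.7 to 12.3 over the 7. For lung endothelium and stroma it stood at 11.5, the highest of the 7. Its share of tumour RNA was not measured, so its low bone transcripts do not show that it kept the type of its primary. Without the FC-28 pair 857 genes passed, and in FC-28 itself 781 of them (91.1%) went the same direction.

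For the count of genes between metastatic and localized primaries, chance was not excluded. In 8 of 100 splits of the 18 primaries into groups of these sizes, the real one included, at least as many genes passed as the real 1. The highest other split gave 847 genes, and its group of 6 held all 4 primaries low in bone transcripts, which points to a structure of the samples. The split by background gave 3 genes, and with background as a covariate C1qtnf1 was still at -1.69 (adjusted p = 0.00798). For the lung metastases, 1 of 64 sign patterns of the 7 pairs, the real one, gave as many as 930 genes, and the highest other gave 0. This argues against chance for the count, but 64 patterns are too few to exclude it. The count includes genes of lung tissue, so it does not show a difference within the tumour cells.

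The hypothesis that lung metastases carry further the same shift as metastatic primaries was tested across genes, which are not independent replicates. The fold changes of the 5 unpaired metastatic primaries against the 6 localized ones and those of the 7 pairs correlated at 0.031 over 10978 genes. Relabelling gave correlations of -0.24 to 0.23, and 38 of the relabellings were as high, so no such shift showed across all genes. The fold changes of the pairs also hold the lung epithelium genes, with a median of 6.31, and the skeletal muscle genes, with -4.14. A correlation over all genes therefore cannot show or exclude a shift within the tumour cells.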
